A study of Rattus norvegicus with 29 samples.

How the data were processed

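The values analysed are the processed signals deposited by the authors for 29 one-colour rat expression arrays, 1 per sample of basolateral amygdala. They are linear intensity values that the authors had scaled per array: the mean without the lowest and highest 2% of probe sets lies between 500.08 and 500.12 on every array. The software and genome build behind that step are not stated in the labels. Medians of the deposited signals range from 210.7 to 292.2, a range of 0.47 on the log2 scale. The choices of test, filter, lists and alternatives were made before the data were examined, apart from the baseline subsets as baselines of their own, the exact permutation of list scores and the interaction tests of lists. So was the rule that a range of log2 medians above 0.2 calls for quantile normalization. That rule applied, so the signals were quantile normalized across the 29 arrays, then raised to a floor of 16 and put on the log2 scale.

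The table holds 15923 probe sets, of which 57 are control probe sets and were left out, leaving 15866. Among these, 12783 carry 1 gene symbol, 312 several and 2771 none in the annotation used. Gene symbols were matched by gene identifier to a current table of rat genes (genome GRCr8) for 12754 probe sets, and 0 symbols changed. Only probe sets with a mean log2 value at or above the 40th percentile (7.26) were tested, which leaves 9520, of which 8043 have 1 symbol. Probe sets with several symbols were tested but are not named as genes, which affects the alpha-globin probe sets.

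The sample labels give 5 groups: 9 baseline arrays without a time, and 5 arrays each of pain, isoflurane, fear conditioning and fear conditioning under isoflurane, taken 6 h after treatment. The abbreviations of the 2 conditioning groups were read through the design text of the series. Rat numbers are given for 15 arrays only, so replicates are not stated to be separate animals for all arrays. A labelling kit is named for the baseline and isoflurane arrays only, and the isoflurane arrays carry later sample numbers than the others. Whether another kit was used for the other 3 groups is not stated. Pain, conditioning or conditioning under isoflurane minus baseline, and conditioning under isoflurane minus isoflurane, therefore cannot be told apart from such a difference. A kit difference would cancel in the interaction. A difference tied to the later sample numbers of the isoflurane arrays would not. It would also enter isoflurane minus baseline and conditioning under isoflurane minus isoflurane.

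Each probe set was fitted with limma (lmFit, then eBayes with a trend of variance on intensity) on all 29 arrays with 1 mean per group. There were 7 contrasts of 2 groups, 1 interaction contrast and a moderated F test over the 5 groups on 4 degrees of freedom. The interaction is the effect of conditioning with isoflurane minus its effect without, that is (conditioning under isoflurane minus isoflurane) minus (conditioning minus baseline). P-values were adjusted by Benjamini-Hochberg over the 9520 probe sets, with 0.05 as the threshold. Standard errors of log2 differences come from this fit, and spreads given with group means are standard deviations (SD) over arrays.

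Gene lists were tested on 7049 genes, with probe sets of the same gene averaged on the log2 scale. The 25 lists, written from general knowledge of the genes, are activity-regulated transcription factors; activity-regulated effectors; glutamate receptors and postsynaptic density; GABA-A, glycine and leak potassium channels. They also include GABAergic interneurons, presynaptic vesicle release, memory-linked kinases with phosphatases and CREB, extracellular matrix and synaptic adhesion, monoamine with opioid and peptide receptors, and voltage-gated ion channels. Stress and metabolism are covered by heat shock and chaperones, glucocorticoid-responsive genes, circadian clock, oxidative stress and xenobiotic metabolism, oxidative phosphorylation, ribosomal proteins, and cytokines and acute inflammation. Markers of cells and neighbouring tissue are excitatory projection neurons, striatum, hypothalamus and thalamus, oligodendrocytes and myelin, astrocytes, microglia, vascular and meningeal cells, and choroid plexus and blood. As written, the list of GABA-A, glycine and leak potassium channels also holds the GABA-B receptor genes Gabbr1 and Gabbr2 and the scaffold gene Gphn. Each list was tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison. The same test with the correlation estimated from the data is given beside it, because genes of a list vary together between arrays and the preset value allows for little of this. The limma fry test was also run on the same lists. After adjustment it called 1 list in isoflurane minus baseline, and 0 in each other comparison and in the interaction.

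A list score is the mean, over the members, of the log2 value minus the mean of that gene over all arrays. Scores were compared between groups by exact permutation over all 2002 splits of 9 and 5 arrays (smallest possible p 0.0004995) or all 252 splits of 5 and 5 arrays (smallest possible p 0.0079). This test of scores was added after the data were examined, and so was the camera test on the interaction contrast. Exact permutation p-values are unadjusted unless called adjusted. After adjustment over the 25 lists, 1 list passed in isoflurane minus baseline, 1 in conditioning minus baseline and 0 in each other comparison of 2 groups.

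Genes named in the text follow a rule set before the data were examined. They are the 3 probe sets with the lowest p in each direction of a comparison, since no direction had 3 past the threshold. To these are added the 4 members with the lowest p in each shifted list, and Fos, Egr1, Arc, Bdnf, Fkbp5, Sgk1, Gfap, Mbp and Ttr in every comparison.

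The tests were first run on simulated data with the means and spreads of these arrays. In each simulation 200 probe sets were changed at once, which eases the adjustment of p, so the shares recovered do not carry over to a comparison with few changed genes. Of simulated log2 shifts of 1.00, the fit recovered 92.2% for pain minus baseline and 91.4% for conditioning minus conditioning under isoflurane; of shifts of 0.50, 61.2% and 49.8%. A simulated list shift of 0.20 was recovered in 100% of 20 simulations, with members varying independently. Calculations used R 4.3.3, limma 3.58.1 and statmod 1.5.0. The 4 comparisons with baseline use the same 9 baseline arrays, so their differences share the noise of these arrays. For this reason the overlap and correlation between them were set beside simulated groups without effect and beside comparisons with separate baseline subsets (replicates 1 to 5 and 6 to 9).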

Results

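The basolateral amygdala is the part of the amygdala in which a cue and a painful event become linked during fear conditioning, a form of learning in which a rat comes to fear a signal paired with a shock. Isoflurane is an inhaled anaesthetic. RNA from this tissue was measured with an array, a slide of short DNA probes that reports the levels of many transcripts at once. The 29 arrays cover untreated baseline rats (9) and rats 6 h after pain, isoflurane, conditioning or conditioning under isoflurane (5 each). Replicates are not stated to be separate animals for all arrays, since rat numbers are given for 15 of them. Single-gene differences between the groups were small against their spread: the limma F test over the 5 groups called 0 of 9520 probe sets (lowest adjusted p 0.247), with 700 at unadjusted p under 0.05 where 476 would be so by chance. The median standard error of a log2 difference was 0.13 against baseline and 0.14 between groups of 5.

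Pain left no single transcript past the threshold, while glucocorticoid-responsive, astrocyte, oxidative-stress and ribosomal genes stood higher than at baseline as groups after quantile normalization. With the deposited scaling only the glucocorticoid-responsive list of these 4 passed, and the ribosomal median was below 0. Without a filter the glucocorticoid-responsive list did not pass either. All 4 list shifts were small, and none was past the threshold when the correlation between genes was estimated from the data. Fkbp5, a co-chaperone induced by glucocorticoids, was among the genes with the lowest p.

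In pain minus baseline, limma called 0 probe sets (lowest adjusted p 0.0704), with 853 at unadjusted p under 0.05, 412 higher and 441 lower. The lowest p-values among higher genes belong to Fnbp1, an actin-membrane adaptor (log2 difference 0.90, SE 0.21, adjusted p 0.148), Fam98c (0.48, SE 0.12, adjusted p 0.303) and Fkbp5 (0.50, SE 0.13, adjusted p 0.303). Fkbp5 averaged 8.94 (SD 0.31) after pain and 8.44 (SD 0.22) at baseline. Among lower genes, Hbb, a beta-globin, differed by -1.19 (SE 0.24, adjusted p 0.0704), Epb41, a protein of the red-cell membrane skeleton, by -0.71 (SE 0.14, adjusted p 0.0704) and Trappc8 by -0.73 (SE 0.15, adjusted p 0.0818). Hbb averaged 10.71 (SD 0.28) after pain against 11.90 (SD 0.52) at baseline. None of these 6 passed the threshold. The baseline arrays differ in Hbb themselves, with means of 11.52 in replicates 1 to 5 and 12.38 in replicates 6 to 9. With arrays centred on their medians, which moves the median of all genes by -0.11, Hbb (adjusted p 0.0388), Epb41 (0.0491) and Trappc8 (0.0394) passed, and Hbb did so at the 70th percentile (0.0455). With baseline replicates 6 to 9 alone all 3 passed (0.00181, 0.0255 and 0.0263).

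The glucocorticoid-responsive list (19 genes) rose after pain with a median log2 difference of 0.09, and 16 of 19 genes were higher (limma adjusted p 0.00522). With estimated correlation its adjusted p was 0.502, and 1 member, Fkbp5, passed adjustment over the list alone while 0 passed over all genes. Its members with the lowest p were Fkbp5 (0.50), Sult1a1 (0.61), S100b (0.14) and Klf9, a transcription factor induced by corticosterone (0.22). Astrocyte markers (22 genes) rose with a median of 0.11 and 17 of 22 higher (limma adjusted p 0.00522; with estimated correlation 0.502), with S100b (0.14), Gjb6 (0.46), Apoe (0.11) and Ntsr2 (0.23). Oxidative-stress genes (28) had a median of 0.09 and 19 of 28 higher (limma adjusted p 0.0446; with estimated correlation 0.502), among them Gsta1 (0.36), Sod3 (0.36), Cat (0.29) and Cyp2d4 (0.24). Ribosomal-protein genes (40) had a median of 0.07 and 30 of 40 higher (limma adjusted p 0.00182; with estimated correlation 0.502), among them Rpl4 (0.19), Rpl7 (0.16), Rpsa (0.19) and Rpl14 (0.24). The glucocorticoid call was lost without a filter (median 0.06, adjusted p 0.343), at the 70th percentile (0.0540), with the replicate block (0.0840) and with baseline replicates 1 to 5 alone (0.0795). With the deposited scaling the astrocyte list had a median of 0.04 (adjusted p 0.319) and the oxidative-stress list one of 0.09 (0.233), and neither passed. The oxidative-stress list was also lost without a filter (0.256), at the 70th percentile (0.0540), with the replicate block (median 0.05, adjusted p 0.129) and with baseline replicates 1 to 5 (0.135) or 6 to 9 (0.0855) alone. The astrocyte list was also lost with the replicate block (0.0840) and with baseline replicates 1 to 5 alone (median 0.06, adjusted p 0.0795). The ribosomal median was -0.0041 (adjusted p 0.804) with the deposited scaling. It was -0.13 (adjusted p 0.221) with arrays centred on their medians, a scaling that moves the median of all genes by -0.11. With arrays centred on their medians, the medians of the glucocorticoid, astrocyte and oxidative-stress lists in pain minus baseline were -0.03, -0.09 and -0.03, below 0 but above that shift; the astrocyte (0.274) and oxidative-stress (0.158) calls were lost. Without pain replicate 1 none of the 4 lists passed. The limma adjusted p was then 0.136 for ribosomal, 0.141 for astrocyte, 0.241 for glucocorticoid-responsive and 0.241 for oxidative-stress genes. In the same order the medians were 0.03, 0.08, 0.06 and 0.08. The oxidative-stress list was also lost without baseline replicate 4 (0.194), 6 (0.0591) or 9 (0.0623) or pain replicate 2 (0.0705). In the astrocyte, oxidative-stress and ribosomal lists, 0 members passed adjustment over the list alone or over all genes.

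After isoflurane alone 1 transcript, Insig1, stood lower than at baseline, and the glucocorticoid-responsive genes stood higher as a group. Insig1 encodes a membrane protein of the endoplasmic reticulum that restrains cholesterol synthesis. The shift of the glucocorticoid list was the only one of the comparison and the only one in the study that also passed with estimated correlation. Immediate early genes such as Fos and Arc did not pass the threshold at 6 h, and earlier times were not measured.

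In isoflurane minus baseline, limma called 1 probe set of 9520, with 512 at unadjusted p under 0.05 (251 higher, 261 lower). Insig1 fell by 0.44 (SE 0.08, adjusted p 0.0179), from 9.87 (SD 0.11) at baseline to 9.42 (SD 0.08), and all 5 isoflurane arrays lay below the baseline mean. The call of Insig1 was lost with arrays centred on their medians (adjusted p 0.0718), with baseline replicates 1 to 5 alone (0.155), with the replicate number as a block, which also takes out baseline replicates 6 to 9 (0.166), in a fit of the 2 groups only (0.302), and without isoflurane replicate 1 (0.180), 3 (0.0505), 4 (0.0624) or 5 (0.109). In these settings the log2 difference stayed between -0.41 and -0.48. Rabep1 (-0.43, SE 0.11) and Ttll5 (-0.55, SE 0.14) had the next lowest p among lower genes and did not pass (adjusted p 0.722 for each). Neither did the 3 higher genes with the lowest p, Zfp644 (0.49, SE 0.13), Lrrc51 (0.80, SE 0.22) and Ctnnd1, a catenin of cell junctions (0.50, SE 0.14), each with adjusted p 0.722.

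The glucocorticoid-responsive list rose with a median of 0.19 and 17 of 19 genes higher (limma adjusted p 9.9e-08; with estimated correlation 0.0290; fry adjusted p 0.0319). Adjusted over the list alone 4 members were higher, while over all genes 0 were. Gpd1, a glycerol phosphate dehydrogenase, differed by 0.36, the metallothionein Mt2A by 0.52, Fkbp5 by 0.43 and Klf9 by 0.30. The list score averaged 0.124 (SD 0.110) after isoflurane and -0.117 (SD 0.098) at baseline. Every isoflurane score (lowest 0.0216) was above every baseline score (highest 0.00257), which gives the smallest possible p of the exact permutation test, 0.0004995 (adjusted over the 25 lists 0.0125).

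**Figure D1:**
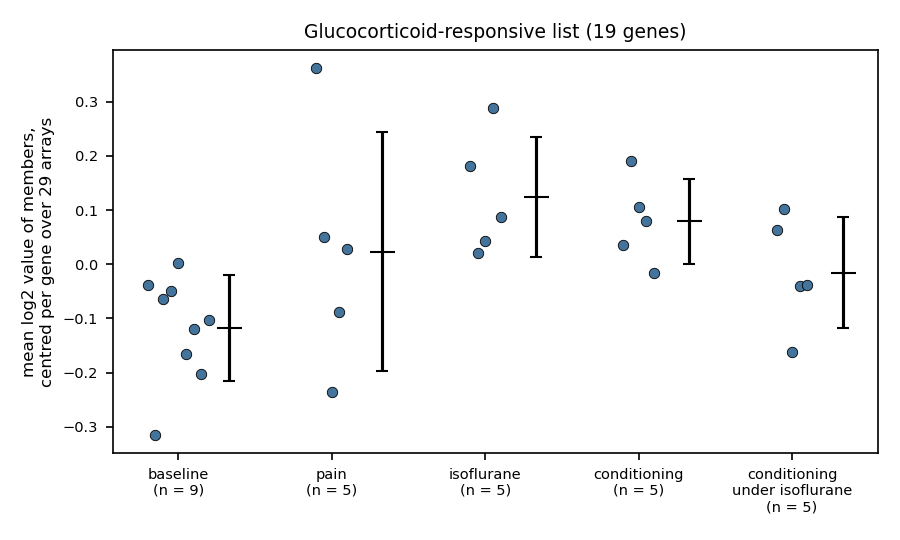
Score of the glucocorticoid-responsive list (19 genes) on each of the 29 arrays, by group, with mean and SD. The score is the mean over the genes of the log2 value minus the mean of that gene over all arrays.

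Conditioning minus baseline had 6 list shifts, 3 of them of glial genes. Oligodendrocyte, astrocyte and microglial markers all rose, as did glucocorticoid-responsive and extracellular-matrix genes. The mixed list of GABA-A, glycine and leak potassium channels was the only one to fall. No single gene passed, and none of the 6 lists passed with estimated correlation.

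In conditioning minus baseline, limma called 0 probe sets (lowest adjusted p 0.415), with 966 at unadjusted p under 0.05, 487 higher and 479 lower. The lowest p-values belong to Cnn3, an actin-binding calponin (0.54, SE 0.12), the small heat-shock protein Cryab (0.55, SE 0.14) and the glutathione transferase Gstt3 (0.40, SE 0.10) among higher genes. Ier5l (-0.59, SE 0.13), Slc45a4 (-0.66, SE 0.16) and Hagh, a glyoxalase (-0.36, SE 0.09), hold this place among lower genes. Each of these 6 has adjusted p 0.415. Ier5l averaged 7.15 (SD 0.14) after conditioning and 7.74 (SD 0.15) at baseline.

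Oligodendrocyte and myelin markers (17 genes) rose with a median of 0.23 and 16 of 17 higher (limma adjusted p 1.8e-06; with estimated correlation 0.201). The myelin proteolipid Mal (0.54), the deacetylase Sirt2 (0.25), Mog (0.39) and the lineage factor Sox10 (0.38) had the lowest p, and 2 members passed adjustment over the list alone while 0 passed over all genes. Astrocyte markers rose with a median of 0.16 and 21 of 22 higher (limma adjusted p 2.2e-06; with estimated correlation 0.201), with the gap-junction protein Gjb6 (0.60), Gfap (0.40), Vim (0.93) and Glul (0.20). Glucocorticoid-responsive genes rose with a median of 0.20 and 18 of 19 higher (limma adjusted p 9.3e-05; with estimated correlation 0.201), with Klf9 (0.29), Hsd11b1, which regenerates corticosterone (0.43), Gpd1 (0.24) and the cell-cycle inhibitor Cdkn1a (0.92). By exact permutation the glucocorticoid score had p 0.0020 (adjusted 0.04995), the oligodendrocyte score p 0.0789 and the astrocyte score p 0.0270. After adjustment over the 25 lists, only the glucocorticoid list passed this test in conditioning minus baseline. The oligodendrocyte score differed by 0.139 from baseline replicates 1 to 5 (exact permutation p 0.349) and by 0.325 from replicates 6 to 9 (exact permutation p 0.0397).

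Extracellular-matrix and adhesion genes (26) rose by a median of 0.10, 16 of 26 higher (limma adjusted p 0.0326; with estimated correlation 0.201; exact permutation p 0.00749). Plat, the tissue plasminogen activator (0.67), Sparc (0.53), Fn1 (0.41) and Timp3 (0.26) had the lowest p in this list. Microglial markers (14) rose by a median of 0.12, 11 of 14 higher (limma adjusted p 0.0326; with estimated correlation 0.521; exact permutation p 0.310), with B2m (0.22), Aif1 (0.24), C1qa (0.25) and C1qb (0.24). The list of GABA-A, glycine and leak potassium channels (15) fell, with a median of -0.21 and 11 of 15 lower (limma adjusted p 0.0326; with estimated correlation 0.232; exact permutation p 0.0320). Gabra4 (-0.58), Glra2 (-0.51), Gabrb2 (-0.22) and Glrb (-0.39) had the lowest p; over the list alone 2 members were lower and 1 higher, and over all genes 0. The extracellular-matrix list was lost without baseline replicate 2 (0.0501) or 8 (0.0539) or conditioning replicate 1 (0.0789) or 3 (0.102). It was also lost with the deposited scaling (0.0565), at the 70th percentile (0.0536), with the replicate block (median 0.05, adjusted p 0.128) and with either baseline subset alone (0.113 for replicates 1 to 5, 0.0995 for 6 to 9). The channel list was lost without baseline replicate 3 (0.0601) or 6 (0.0568) or conditioning replicate 1 (0.0789) or 2 (0.126). Its medians in these runs, in the same order, were -0.21, -0.15, -0.13 and -0.16. Against baseline replicates 6 to 9 alone the channel median was -0.13 (adjusted p 0.285; exact permutation p 0.214), and with the filter at the 70th percentile -0.12 (adjusted p 0.413). Microglial markers no longer passed without baseline replicate 6 (0.0641) or 7 (0.0633) or conditioning replicate 1 (0.141) or 2 (0.335), without a filter (median 0.04, adjusted p 0.0812) or with the replicate block (median 0.06, adjusted p 0.240). With baseline replicates 1 to 5 alone the microglial median was 0.06 (adjusted p 0.214) and the score difference 0.0323 (exact permutation p 0.738). Leaving out any 1 array kept the oligodendrocyte, astrocyte and glucocorticoid-responsive lists past the threshold; without conditioning replicate 2 the astrocyte median was 0.08 and the glucocorticoid median 0.12. No member of the glucocorticoid, astrocyte, extracellular-matrix or microglial list passed, whether adjusted over the list alone (0) or over all genes (0).

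After conditioning under isoflurane the genes of the respiratory chain stood lower than at baseline as a group. Vascular, astrocyte and glucocorticoid-responsive genes stood higher than at baseline, and oligodendrocyte markers did not pass. None of the 4 lists passed with estimated correlation, and no single gene passed.

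In conditioning under isoflurane minus baseline, limma called 0 probe sets (lowest adjusted p 0.372), with 619 at unadjusted p under 0.05 (309 higher, 310 lower). Opcml, a neural adhesion molecule (0.50, SE 0.12), the phospholipid flippase Atp9b (0.43, SE 0.10) and Secisbp2l (0.49, SE 0.12) had the lowest p among higher genes, each with adjusted p 0.372. Lower genes with the lowest p were Vps11 of the endosomal tethering complexes (-0.57, SE 0.12, adjusted p 0.372), Rrp1 (-0.74, SE 0.17, adjusted p 0.372) and the mitochondrial ribosomal gene Mrps23 (-0.47, SE 0.12, adjusted p 0.448).

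Oxidative-phosphorylation genes (42) fell, with a median of -0.07 and 36 of 42 lower (limma adjusted p 0.000388; with estimated correlation 0.484; exact permutation p 0.00649). Sdha (-0.25) and Sdhc (-0.27) of complex II, Cox4i1 of complex IV (-0.10) and Atp5f1a of ATP synthase (-0.14) had the lowest p. By exact permutation no list of this comparison passed after adjustment over the 25 lists. Glucocorticoid-responsive genes rose by a median of 0.12, 15 of 19 higher (limma adjusted p 0.0337; with estimated correlation 0.591), with S100b (0.12), Gpd1 (0.19), Fkbp5 (0.23) and Mt2A (0.24). Astrocyte markers rose by a median of 0.09, 18 of 22 higher (limma adjusted p 0.0234; with estimated correlation 0.787), with Gfap (0.34), S100b (0.12), Gjb6 (0.42) and Vim (0.52). Vascular and meningeal markers (15) rose by a median of 0.16, 11 of 15 higher (limma adjusted p 0.0337; with estimated correlation 0.591), with the tight-junction claudin Cldn5 (0.44), the pericyte gene Rgs5 (0.34), Esam (0.36) and Slc2a1 (0.23). The respiratory list passed without any 1 array, and the 3 others did not. Glucocorticoid-responsive genes were lost without baseline replicate 2 (0.0760), 6 (0.0675), 7 (0.0712) or 8 (0.0628) or conditioning-under-isoflurane replicate 1 (0.164) or 2 (0.211). Astrocyte markers were lost without baseline replicate 1 (0.103), 6 (0.0675) or 7 (0.0712) or conditioning-under-isoflurane replicate 1 (0.0949) or 2 (0.211). Their medians in these runs, in the same order, were 0.05, 0.07, 0.06, 0.08 and 0.07. Vascular markers were lost without baseline replicate 3 (0.124), 5 (0.0763), 6 (0.0557), 7 (0.0712) or 8 (0.0628) or conditioning-under-isoflurane replicate 2 (0.121) or 3 (0.429), and without that replicate 3 their median was 0.0052. The glucocorticoid call was also lost with the deposited scaling (0.0926), centred arrays (0.0731), no filter (median 0.06, adjusted p 0.300), the 70th percentile (0.323), the replicate block (0.315) and baseline replicates 1 to 5 alone (median 0.05, adjusted p 0.303). The astrocyte call was also lost with the deposited scaling (median 0.06, adjusted p 0.366), centred arrays (median 0.02, adjusted p 0.323), the replicate block (0.279) and baseline replicates 1 to 5 alone (median 0.04, adjusted p 0.254). Vascular markers were also lost with the replicate block (0.188) and with baseline replicates 1 to 5 (0.139) or 6 to 9 (0.107) alone. In these 4 lists 0 members passed over the list alone and 0 over all genes.

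Oligodendrocyte genes were the 1 list shifted between conditioning and pain, higher after conditioning, and they did not pass with estimated correlation (adjusted p 0.654). The comparison sets learning with a painful stimulus beside pain alone. The rat numbers of these groups do not overlap, with 9 to 13 for pain and 24 to 31 for conditioning. A difference tied to these numbers cannot be told apart from an effect of conditioning. Plagl2, a zinc-finger transcription factor, had the lowest p of all genes without passing.

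In conditioning minus pain, limma called 0 probe sets, with 861 at unadjusted p under 0.05 (451 higher, 410 lower). Plagl2 differed by 1.00 (SE 0.19, adjusted p 0.0937), averaging 7.86 (SD 0.10) after conditioning and 6.86 (SD 0.37) after pain. Ppp1r18, a phosphatase subunit (0.98, SE 0.21, adjusted p 0.242), and the kinesin Kif1c (0.70, SE 0.16, adjusted p 0.356) follow among higher genes. On the lower side stand Ier5l (-0.73, SE 0.15, adjusted p 0.162), Fam98c (-0.54, SE 0.14, adjusted p 0.356) and the coagulation inhibitor Tfpi (-0.58, SE 0.15, adjusted p 0.356). Plagl2 passed only without the variance trend (limma adjusted p 0.0448) or without pain replicate 2 (0.0450). Ier5l did so without the trend (0.0452) or without pain replicate 1 (0.0351), and Ppp1r18 without pain replicate 4 (0.00056). Oligodendrocyte markers rose by a median of 0.25, 16 of 17 higher (limma adjusted p 0.00134; with estimated correlation 0.654; exact permutation p 0.111), while 0 members passed over the list alone and 0 over all genes. Cnp (0.27), Mog (0.37), Pmp22 (0.30) and Sirt2 (0.16) had the lowest p in it. Without pain replicate 1 its adjusted p was 0.0547.

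Oligodendrocyte and chaperone genes were higher after conditioning without isoflurane than with it. Astrocyte and microglial markers were also higher without it, and presynaptic genes were lower; none of the 5 lists passed with estimated correlation (adjusted p 0.375 to 0.591). Differences of single genes were no more frequent than by chance.

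In conditioning minus conditioning under isoflurane, limma called 0 probe sets (lowest adjusted p 0.999), with 351 at unadjusted p under 0.05 (181 higher, 170 lower) where 476 would be so by chance. Apod, a lipocalin (0.64, SE 0.18), the RNA-destabilizing Zfp36 (0.63, SE 0.18) and Cfdp1 (0.51, SE 0.15) had the lowest p among higher genes. Among lower genes these were Rpp25 (-0.72, SE 0.21), Zfp330 (-0.37, SE 0.12) and Mapt, which encodes tau (-0.32, SE 0.10); adjusted p was 0.999 for all 6.

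Oligodendrocyte markers were higher without isoflurane by a median of 0.25, 16 of 17 genes in this direction (limma adjusted p 2.5e-07; with estimated correlation 0.375; exact permutation p 0.0952). Cldn11 (0.36), Mal (0.34), Mobp (0.34) and Mog (0.34) had the lowest p in this list. Heat-shock and chaperone genes (35) had a median of 0.06 and 28 of 35 higher (limma adjusted p 0.00129; with estimated correlation 0.375; exact permutation p 0.0476), with Cryab (0.52), the endoplasmic-reticulum chaperones Hspa5 (0.43) and Pdia6 (0.17), and Serpinh1 (0.51). Astrocyte markers had a median of 0.09, 18 of 22 higher (limma adjusted p 0.0429; with estimated correlation 0.591), with Fabp7 (0.40), Slc1a3 (0.17), Aqp4 (0.19) and Glul (0.14). Microglial markers had a median of 0.10, 12 of 14 higher (limma adjusted p 0.0429; with estimated correlation 0.591), with Csf1r (0.25), Ctss (0.23), Tyrobp (0.23) and Aif1 (0.15). Presynaptic genes (27) had a median of -0.10, 18 of 27 lower (limma adjusted p 0.0429; with estimated correlation 0.591), with Sncb (-0.39), the synaptobrevin Vamp2 (-0.33), Dnm1 (-0.18) and Sv2b (-0.56). By exact permutation no list of this comparison passed after adjustment over the 25 lists. In the limma test at the preset correlation, oligodendrocyte and chaperone genes passed without any 1 array. Over all runs, other scalings included, the chaperone median ranged from 0.02 to 0.10 and the oligodendrocyte median from 0.17 to 0.29. Astrocyte markers were lost without conditioning replicate 2 (0.640) or conditioning-under-isoflurane replicate 4 (0.265) or 5 (0.219). Microglial markers were lost without conditioning replicate 1 (0.240) or 2 (0.602) or conditioning-under-isoflurane replicate 1 (0.154), 2 (0.0543), 4 (0.0870) or 5 (0.219). Without conditioning replicate 2 the medians were 0.03 for astrocyte and 0.01 for microglial markers and -0.03 for presynaptic genes. Presynaptic genes were lost without conditioning replicate 2 (0.602), 4 (0.118) or 5 (0.0708) or conditioning-under-isoflurane replicate 3 (0.0504), 4 (0.265) or 5 (0.109). They were also lost with the deposited scaling (0.0510), centred arrays (0.0825) and no filter (0.350). Microglial markers were also lost with the deposited scaling (0.0510) and no filter (0.204), and astrocyte markers with no filter (0.230). In these 5 lists 0 members passed over the list alone and 0 over all genes.

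**Figure D2:**
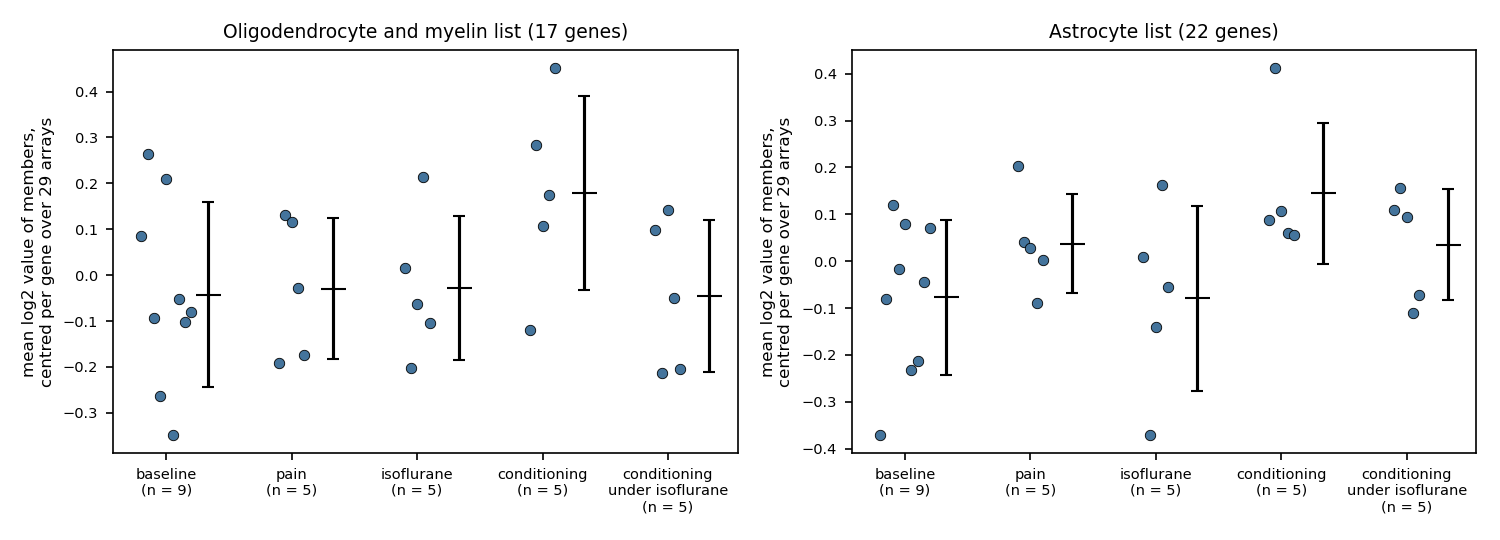
Scores of the oligodendrocyte and myelin list (17 genes) and of the astrocyte list (22 genes) on each of the 29 arrays, by group, with mean and SD.

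Glucocorticoid-responsive and respiratory-chain genes stood lower after conditioning under isoflurane than after isoflurane alone, and vascular and astrocyte genes higher. The later sample numbers of the isoflurane arrays and a possible kit difference cannot be told apart from an effect of conditioning here. No single gene passed, and none of the 4 lists passed with estimated correlation.

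In conditioning under isoflurane minus isoflurane, limma called 0 probe sets (lowest adjusted p 0.781), with 381 at unadjusted p under 0.05 (179 higher, 202 lower). The lowest p-values belong to the mitochondrial ribosomal gene Mrps6 (-0.65, SE 0.15, adjusted p 0.781) and Zfp644 (-0.63, SE 0.15, adjusted p 0.781), followed on the lower side by mrpl11 (-0.32, SE 0.08, adjusted p 0.998). Higher genes with the lowest p were Atp9b (0.46, SE 0.11, adjusted p 0.991), Rabep1 (0.47, SE 0.12, adjusted p 0.998) and the guanine deaminase Gda (0.56, SE 0.15, adjusted p 0.998).

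Glucocorticoid-responsive genes fell, with a median of -0.14 and 14 of 19 lower (limma adjusted p 0.0311; with estimated correlation 0.514; exact permutation p 0.0714). Ddit4, an inhibitor of mTOR signalling (-0.40), the kinase Sgk1 (-0.45), the phosphatase Dusp1 (-0.46) and Mt2A (-0.28) had the lowest p. Oxidative-phosphorylation genes fell, with a median of -0.04 and 32 of 42 lower (limma adjusted p 0.0193; with estimated correlation 0.514), with Cox5a (-0.74), Uqcrfs1 (-0.17), Sdhd (-0.13) and Cox4i1 (-0.09). Vascular and meningeal markers rose by a median of 0.19, 13 of 15 higher (limma adjusted p 0.0193; with estimated correlation 0.514), with Mgp (0.45), Esam (0.33), Aldh1a2 (0.39) and Col1a1 (0.28). Astrocyte markers rose by a median of 0.09, 17 of 22 higher (limma adjusted p 0.0486; with estimated correlation 0.739), with Atp1b2 (0.73), Fgfr3 (0.27), Gfap (0.24) and Slc7a10 (0.21). Atp1b2 was 6.33 on isoflurane replicate 2, against 9.34 on the nearest array of the group. Each of these list calls was lost without isoflurane replicate 1 (0.0594 for all 4) and without conditioning-under-isoflurane replicate 3 (0.105 for all 4). Glucocorticoid-responsive genes were also lost without conditioning-under-isoflurane replicate 4 (0.0730) or 5 (0.128) or isoflurane replicate 4 (0.339). Their median was -0.05 without conditioning-under-isoflurane replicate 3 and -0.08 without replicate 5. The call was also lost without a filter (0.0804). Respiratory genes were also lost without conditioning-under-isoflurane replicate 1 (0.0567) or isoflurane replicate 2 (0.148) or without a filter (0.0697). Astrocyte markers were also lost without conditioning-under-isoflurane replicate 1 (0.152) or 2 (0.267) or isoflurane replicate 2 (0.522, median 0.01) or 3 (0.115). The astrocyte call was lost too with the deposited scaling (0.0727), 32 added before taking logs (0.0518), no filter (0.0802) and the 70th percentile (median 0.05, adjusted p 0.154). Over the list alone 0 members of the 4 lists passed, and over all genes 0.

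The effect of conditioning on the glucocorticoid and oligodendrocyte genes differed with and without isoflurane in an interaction test at the preset correlation. With estimated correlation neither list passed (adjusted p 0.0509 and 0.579). Without the anaesthetic both lists were higher after conditioning, while with it the glucocorticoid list was lower. The mean glucocorticoid score was highest after isoflurane alone (0.124). It was -0.117 at baseline, 0.079 after conditioning and -0.015 after conditioning under isoflurane. The isoflurane arrays carry later sample numbers, and a difference tied to this would not cancel in the interaction. Single genes with an interaction were no more frequent than by chance.

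In the interaction, limma called 0 probe sets (lowest adjusted p 0.572), with 456 at unadjusted p under 0.05 (227 higher, 229 lower). Zfp644 (-0.90, SE 0.19, adjusted p 0.572), Lrrc51 (-1.21, SE 0.33, adjusted p 0.959) and Bbox1, an enzyme of carnitine synthesis (-1.52, SE 0.41, adjusted p 0.959), had the lowest p on the lower side. Caprin1 (0.49, SE 0.15), Zhx1 (0.45, SE 0.14) and Reps1 (0.60, SE 0.18) did so on the higher side, each with adjusted p 0.959. In a test added after the data were examined, glucocorticoid-responsive genes had a median interaction of -0.29, and all 19 were below 0 (limma adjusted p 8.2e-07; with estimated correlation 0.0509). Klf9 (-0.44), Gpd1 (-0.41), Fkbp5 (-0.48) and Mt2A (-0.57) had the lowest p in the list. Oligodendrocyte markers had a median interaction of -0.23, 15 of 17 below 0 (limma adjusted p 9.0e-05; with estimated correlation 0.579), with Mal (-0.67), Mog (-0.51), Cldn11 (-0.49) and Sirt2 (-0.23). Both lists passed without any 1 array. In both lists 0 members passed over the list alone and 0 over all genes.

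Genes chosen in advance as markers of neuronal activity, glucocorticoid action, glia and neighbouring tissue did not pass in any comparison. Treated arrays were taken only at 6 h, so an earlier change of activity genes that had ended by then would not be seen. With baseline replicates 6 to 9 alone, 1 of them passed, Gfap after conditioning (0.58, adjusted p 0.0458). Values are averages over the probe sets of a gene that passed the filter, 1 for Fos. Fos, the immediate early gene of neuronal activity, averaged 7.95 (SD 0.92) at baseline, 7.81 (SD 0.80) after pain, 8.26 (SD 0.20) after isoflurane, 7.89 (SD 0.36) after conditioning and 7.86 (SD 0.72) after conditioning under isoflurane. Its log2 differences from baseline, in the same order, were -0.14, 0.31, -0.06 and -0.09 (limma adjusted p 0.944, 0.986, 0.966 and 0.983). Arc, a synaptic immediate early gene, differed by 0.01, 0.15, -0.06 and -0.02 (adjusted p 0.986, 0.986, 0.922 and 0.987), and the growth factor Bdnf by -0.34, 0.01, -0.38 and -0.27 (adjusted p 0.661, 0.999, 0.565 and 0.892). Egr1 differed by -0.14, -0.13, -0.35 and -0.17, with its lowest adjusted p (0.396) after conditioning. Sgk1 differed by -0.03, 0.21, 0.08 and -0.23 (adjusted p 0.982, 0.986, 0.915 and 0.892), and Fkbp5 by 0.50, 0.43, 0.28 and 0.23. Gfap differed by 0.27, 0.10, 0.40 and 0.34 (adjusted p 0.552, 0.994, 0.396 and 0.695), and Mbp, the myelin basic protein, by 0.15, 0.01, 0.25 and 0.08 (adjusted p 0.731, 0.998, 0.483 and 0.959). Ttr, the transthyretin of the choroid plexus, differed by -0.58, -0.84, -0.31 and -0.07 (adjusted p 0.857, 0.986, 0.911 and 0.990), with a baseline SD of 2.24 against 0.36 after isoflurane.

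**Figure D3:**
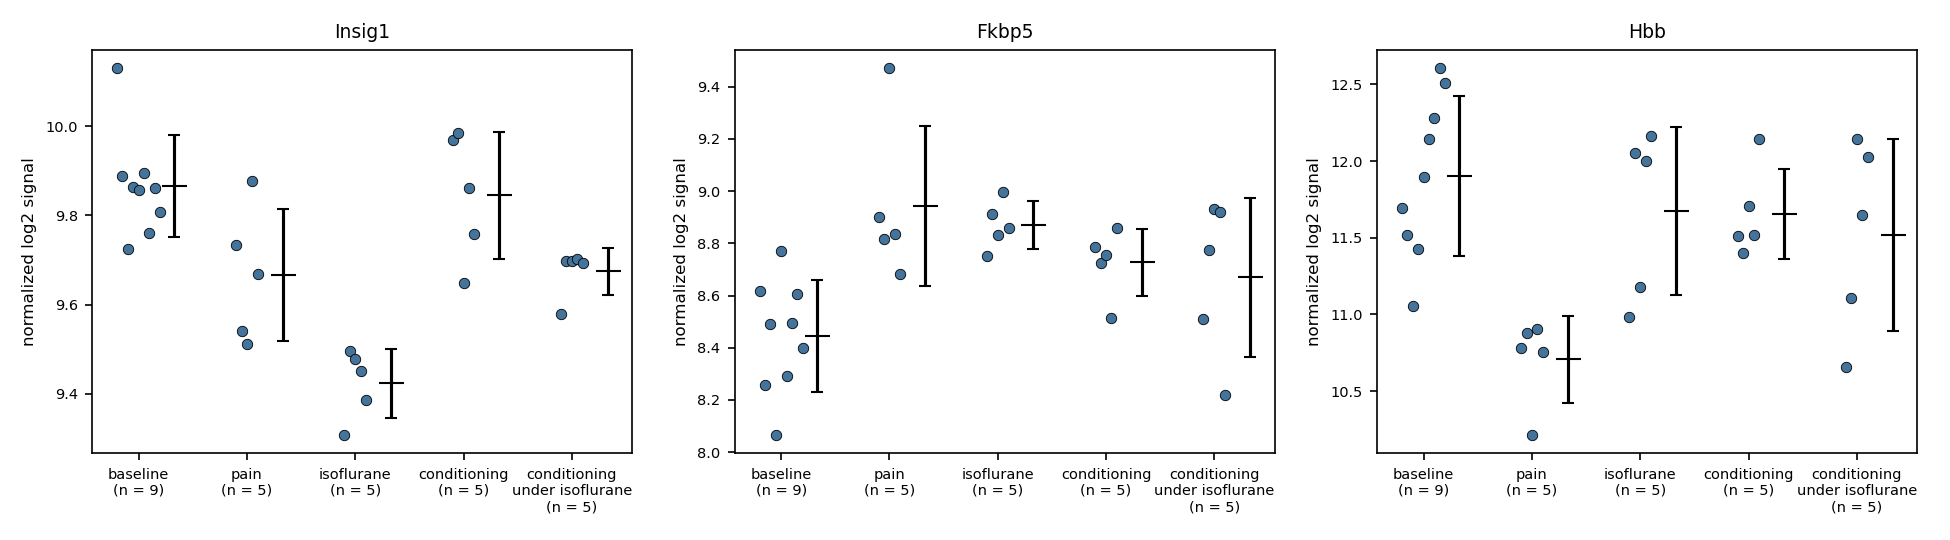
Log2 values of Insig1, Fkbp5 and Hbb on each of the 29 arrays, by group, with mean and SD.

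Between the other pairs of groups the same genes did not pass either. In conditioning minus pain, limma gave Fos 0.08, Arc -0.08, Bdnf -0.04, Egr1 -0.21 and Fkbp5 -0.21 (adjusted p 0.963, 0.922, 0.968, 0.612 and 0.632). Without against with isoflurane during conditioning, Fos differed by 0.03, Arc by -0.04, Bdnf by -0.11, Egr1 by -0.18 and Fkbp5 by 0.06, each with adjusted p 0.998. After conditioning under isoflurane against isoflurane alone, Fos differed by -0.40, Arc by -0.17, Bdnf by -0.28, Egr1 by -0.03 and Fkbp5 by -0.20, each with adjusted p 0.996. In the interaction Fos had -0.34 (adjusted p 0.979), Egr1 0.31 (0.974), Arc -0.11 (0.981), Bdnf 0.10 (0.987), Sgk1 -0.52 (0.974) and Ttr 1.08 (0.974). Sgk1, Gfap, Mbp and Ttr differed by 0.11, 0.12, 0.10 and 0.27 in conditioning minus pain, by 0.31, 0.06, 0.17 and -0.24 between the 2 conditioning groups, and by -0.45, 0.24, 0.07 and 0.76 in conditioning under isoflurane minus isoflurane. Gfap had an interaction of -0.16 (adjusted p 0.976) and Mbp of -0.18 (0.974).

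The 4 treated groups shared 0 called probe sets in their comparisons with baseline. This was the only possible outcome, since only isoflurane minus baseline had a call (1), and it says nothing about shared responses. Log2 differences from baseline correlated between 0.279 (pain and conditioning under isoflurane) and 0.521 (conditioning and conditioning under isoflurane), and simulated groups without effect gave 0.357 through the shared baseline arrays. With separate baseline subsets (replicates 1 to 5 and 6 to 9) the correlations lay between -0.214 and 0.0370. These subsets differ from each other, which lowers such a correlation. Over all 126 splits of the baseline arrays, the mean correlations lay between 0.0024 and 0.169. In a comparison added after the data were examined, baseline replicates 6 to 9 alone gave 160 called probe sets after pain, 29 after isoflurane, 101 after conditioning and 57 after conditioning under isoflurane (limma), and replicates 1 to 5 alone gave 0 in each. The glucocorticoid list was called in all 4 comparisons with baseline at the preset correlation, but with estimated correlation only after isoflurane (adjusted p 0.0290; 0.502 after pain, 0.201 after conditioning and 0.591 after conditioning under isoflurane). These 4 comparisons share the baseline arrays, so part of the likeness comes from them. Against baseline replicates 1 to 5 alone the exact permutation p of its score was 0.349 for pain and 0.349 for conditioning under isoflurane.

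Of the 25 lists, 12 shifted in at least 1 of the 7 comparisons of 2 groups at the preset correlation, and 13 in none. With estimated correlation only the glucocorticoid list passed, in isoflurane minus baseline alone. Activity-regulated transcription factors, the list of Fos and Egr1, had their lowest limma adjusted p, 0.0649, in conditioning under isoflurane minus isoflurane. Activity-regulated effectors such as Arc and Bdnf had 0.0574 in conditioning minus pain, and clock genes 0.0668 in conditioning minus baseline. Lowest adjusted p was 0.0792 for glutamate receptors, 0.0803 for monoamine and peptide receptors, 0.140 for voltage-gated channels and 0.321 for memory-linked kinases. For cell and tissue markers it was 0.0819 (striatum), 0.229 (GABAergic interneurons), 0.433 (choroid plexus and blood), 0.558 (excitatory projection neurons) and 0.765 (hypothalamus and thalamus). Cytokine and acute inflammation genes had 0.453.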

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

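The values below were picked out by a test of each group for a single array lying apart (Dixon's ratio, 5% level) and by the interaction tests of the lists; the interaction tests of lists were chosen after the data were examined. Of 367 groups of values tested, 24 are listed as holding such an array, and about 1 in 20 groups (18.35 of 367) would by chance. A flagged value that a gene gave both as a probe set and as an average is listed once. The 367 count both tests, so 24 and 18.35 are not strictly comparable. No array was left out because of this.

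Pain replicate 3 had a median deposited signal of 292.2, against 244.1 on the next array of its group. Its score on the first principal component was -49.9, against -3.31 on the nearest array. Fkbp5 was highest on this array (9.47 against 8.90 on the next) and Hbb lowest (10.2 against 10.8). Trappc8 was 7.08 there, against 8.19 on the nearest array of the group. The extracellular-matrix score of this array was -0.141, against 0.0155 on the nearest. Without it, limma called 0 probe sets and 4 lists in pain minus baseline.

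Sult1a1 was 9.93 on pain replicate 1, against 8.90 on the next array. At baseline, Trappc8 was 8.34 on replicate 2 (nearest 8.70), Ttr was 13.9 on replicate 1 (nearest 10.4) and Insig1 was 10.1 on replicate 1 (nearest 9.89).

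After isoflurane, Atp1b2 was 6.33 on replicate 2, against 9.34 or more on the 4 others, and the mean after conditioning under isoflurane was 9.51. Replicate 2 also had the highest ribosomal score (0.0781, nearest -0.00997). Replicate 4 had the highest vascular score of the isoflurane group (0.111, nearest -0.143) and the highest value of Mgp (8.12, nearest 7.26).

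After conditioning, replicate 2 had an astrocyte score of 0.411 (nearest 0.108), and replicate 3 had the highest value of Glrb (9.42, nearest 8.72).

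After conditioning under isoflurane, replicate 3 had a GAPDH 3' to 5' ratio of 1.40 (nearest 1.24), a vascular score of 0.470 (nearest 0.0584), a Tyrobp value of 8.79 (nearest 8.08) and an Fgfr3 value of 7.99 (nearest 8.25). Replicate 4 had a score of 0.122 for GABA-A, glycine and leak potassium channels (nearest -0.0368) and a Vim value of 7.64 (nearest 8.96). Replicate 1 had the lowest Mrps23 value (8.87, nearest 9.31) and the highest Mrps6 value (9.89, nearest 9.72).

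The interaction of conditioning and isoflurane had a median of -0.29 over the glucocorticoid-responsive genes, and it kept its sign and its call in all 24 refits without 1 array. Over the oligodendrocyte and myelin genes the median was -0.23, with the same outcome in 24 refits. With estimated inter-gene correlation neither list passed (limma adjusted p 0.0509 and 0.579).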

How the results depend on the processing

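The baseline subsets, the exact permutation of list scores and the interaction tests of lists were chosen after the results were seen; the other alternatives were set beforehand. Where a count changed, the cause was not tested. For the alternative settings, counts that stayed close to the main count are not listed. A list can lose its call while the count stays close.

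Counts of probe sets (limma, adjusted p under 0.05) of pain minus baseline went from 0 to 10 with deposited values centred on each array median and to 4 with the filter at the 70th percentile, all lower after pain. The centred scaling moves the median of all genes by -0.11 in this comparison. For isoflurane minus baseline the count went from 1 to 0 with centred values, with the replicate block, with only the groups of the comparison and with baseline replicates 1 to 5 alone. Numbers 6 to 9 occur at baseline only, so the replicate block also takes these 4 arrays out of comparisons with baseline, and its changes there are not put down to the block. Conditioning minus pain went from 0 to 2 without the variance trend (1 higher, 1 lower), and the F test from 0 to 2 without a filter. With baseline replicates 6 to 9 alone the counts were 160 (84 higher) for pain, 29 (15 higher) for isoflurane, 101 (55 higher) for conditioning and 57 (35 higher) for conditioning under isoflurane; with replicates 1 to 5 alone they were 0 for all 4. Rat number as a covariate left the count of conditioning minus conditioning under isoflurane at 0.

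Leaving out each array in turn gave 0 to 6 probe sets for pain minus baseline (6 without baseline replicate 3, 5 without baseline replicate 4, 2 without pain replicate 4). It gave 0 to 1 for isoflurane minus baseline (0 without isoflurane replicate 1, 3, 4 or 5). Conditioning minus pain had 0 to 3 (3 without pain replicate 4, 2 without pain replicate 1, 1 without pain replicate 2 or conditioning replicate 5), and the F test 0 to 1 (1 without pain replicate 4). All other comparisons stayed at 0.

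Counts of lists for pain minus baseline went from 4 to 2 without a filter, at the 70th percentile, with the replicate block and with baseline replicates 1 to 5 alone, and to 0 with estimated inter-gene correlation and by exact permutation. Isoflurane minus baseline went from 1 to 2 with the replicate block and 3 with baseline replicates 1 to 5 alone. Conditioning minus baseline went from 6 to 0 with estimated correlation and 1 by exact permutation. Conditioning under isoflurane minus baseline went from 4 to 2 with centred values or the 70th percentile and to 0 with estimated correlation or exact permutation. Conditioning minus pain went from 1 to 2 with the deposited scaling, centred values, the 70th percentile or the replicate block, and to 0 with estimated correlation or exact permutation. Conditioning minus conditioning under isoflurane went from 5 to 3 with the deposited scaling, 2 without a filter, and 0 with estimated correlation or exact permutation. Conditioning under isoflurane minus isoflurane went from 4 to 1 without a filter, 2 at the 70th percentile, and 0 with estimated correlation or exact permutation. Ribosomal genes after pain reversed, to -0.0041 with the deposited scaling and -0.13 with centred values.

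Leaving out each array in turn gave 0 to 6 lists for pain, 1 to 3 for isoflurane, 3 to 10 for conditioning and 1 to 5 for conditioning under isoflurane against baseline. It gave 0 to 3 for conditioning minus pain, 2 to 8 for conditioning minus conditioning under isoflurane, and 0 to 7 for conditioning under isoflurane minus isoflurane. The extremes came without pain replicate 1 (0) and baseline replicate 1 (6); isoflurane replicate 5 (3); conditioning replicate 1 (3), and baseline replicate 9 or conditioning replicate 4 (10). For the others they came without baseline replicate 6 or 7 or conditioning-under-isoflurane replicate 2 (1) and baseline replicate 4 (5); pain replicate 1 (0) and conditioning replicate 3 (3); conditioning replicate 2 or conditioning-under-isoflurane replicate 4 or 5 (2) and conditioning replicate 3 (8); isoflurane replicate 1 or conditioning-under-isoflurane replicate 3 (0) and isoflurane replicate 5 (7).

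Over 7 settings other than estimated correlation, every setting kept the glucocorticoid list (isoflurane, conditioning, interaction), the oligodendrocyte list (all of its calls), the astrocyte list (conditioning), chaperones, and respiratory genes against baseline; vascular genes passed in all 6 run for conditioning under isoflurane minus isoflurane. The fewest, 2 of 7, kept oxidative-stress genes after pain and the glucocorticoid list after conditioning under isoflurane, and 3 of 7 kept astrocyte genes in conditioning under isoflurane minus isoflurane.

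Over named genes, 5161 values were unchanged in call, 28 gained and 8 lost a call, 114 uncalled values changed sign, and 0 called values reversed; over lists, 457 were unchanged, 147 lost the call and 2 reversed. Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at 0.0015 on average over 50 pairs.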

Other observations

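The comparison of the baseline subsets with each other, the tests of the glucocorticoid list, the exact tests of list scores and the chance test of the myelin list were chosen after the results were seen.

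Clock genes had a median of -0.10 after conditioning, with 11 of 12 lower, without passing (limma adjusted p 0.0668; with estimated correlation 0.201; exact permutation p 0.00799, adjusted over 25 lists 0.0666). The score averaged 0.0622 (SD 0.0689) at baseline and -0.0546 (SD 0.0471) after conditioning. After pain the median was -0.13, with 9 of 12 lower, and the score difference -0.135, also without passing (limma adjusted p 0.0961; with estimated correlation 0.502; exact permutation p 0.0190, adjusted over 25 lists 0.475). Times of day are not stated for any array.

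The 5 baseline arrays numbered 1 to 5 and the 4 numbered 6 to 9 differ from each other. These subsets were set in advance, to give the treated groups separate baselines; they were compared with each other only after the 4th principal component had been seen to part them, and no label names them as batches. In limma 19 probe sets were called, 10 higher and 9 lower in replicates 1 to 5, with 1641 at unadjusted p under 0.05; Pak3 was higher (1.08, SE 0.12, adjusted p 0.00448), Hbb lower (-0.86, SE 0.15), and 4 of the 19 are globins. Of 100 splits of the 9 arrays only this one gave as many (highest other 14), and the globin difference between the subsets accounted for a median of -1.19% of the other called differences (interquartile range -14.6 to 4.29) and the median signal for 12.3% (-17.3 to 19.9). These shares come from slopes within the treated groups. They argue against residual blood as the whole cause of the called differences outside the globins. The test of the median signal does not decide, since its slope leans on pain replicate 3 (log2 median 8.19, next array of its group 7.93). Signal distribution and a difference in dissection, handling or animals stay open and may matter for each comparison with baseline.

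Markers of the hypothalamus and thalamus go with this. Against baseline replicates 1 to 5 the isoflurane score of this list was lower (-0.258, exact permutation p 0.0397), and against replicates 6 to 9 it was higher (0.244, exact permutation p 0.0397). After conditioning the values were -0.254 (exact permutation p 0.0397) and 0.248 (exact permutation p 0.0159). Pain differed by -0.254 and 0.247 (exact permutation p 0.167 and 0.198). Conditioning under isoflurane differed by -0.218 and 0.283 (exact permutation p 0.222 and 0.111). The differences were of similar size in all groups. These exact p-values are unadjusted, so they do not set isoflurane and conditioning apart from pain and conditioning under isoflurane. Over all baseline arrays the mean score was 0.016. It was -0.015 after pain, -0.019 after isoflurane, -0.015 after conditioning and 0.020 after conditioning under isoflurane. The same baseline arrays enter each comparison, so these are not separate results for each group.

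The glucocorticoid list rose after isoflurane by 0.241 in score, and this was tested against 3 technical readings. Against the baseline subset with the smaller difference it still rose by 0.217. Its exact permutation p (0.0079) was bound to be the smallest possible, since every isoflurane score lay above every baseline score. With the 2 genes shared by the glucocorticoid and astrocyte lists left out of both, the astrocyte score changed by -0.0061. The glucocorticoid score without these genes rose by 0.272 (SE 0.0855) more than that. Without Cdkn1a, Mt2A and Sult1a1, and with the shared genes kept, the glucocorticoid list had a difference of 0.178 (exact permutation p 0.0120). Apart from the exact permutation p of 0.0079, these values argue against the baseline subsets, astrocyte RNA and a few genes as the whole cause. As a hypothesis, a stress or anaesthetic response may have raised these genes; the later deposition of the isoflurane arrays, handling and time of day stay open.

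The oligodendrocyte list was higher after conditioning without than with isoflurane at the preset correlation, but did not pass with estimated correlation (limma adjusted p 0.375). Across its 17 genes the difference followed how strongly each gene varies with the others on the remaining 19 arrays at Pearson r 0.413 (0.291 to 0.586 leaving out each gene), which does not decide on more white matter in the dissected tissue. The exact permutation p of the score was 0.0952 (0.0397 to 0.206 leaving out each array), so chance differences in myelin RNA between arrays are not excluded. A change of oligodendrocytes with learning therefore may be present but cannot be told apart from white matter in the sample.

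For isoflurane minus baseline, 8 of 100 splits gave at least the 1 probe set called, so chance is not excluded. The highest other split gave 71, with baseline replicates 4, 6, 7, 8 and 9 as its first group, which points to the structure of the baseline arrays. In the other comparisons 0 probe sets were called (limma; at unadjusted p under 0.05, 853, 966, 619, 861, 351, 381, 456 and 700 for pain, conditioning and conditioning under isoflurane against baseline, conditioning minus pain, conditioning without minus with isoflurane, conditioning under isoflurane minus isoflurane, the interaction and the F test). With a real count of 0 all 100 splits must give as many, so these splits say nothing about chance; the highest other splits gave 5, 2, 10, 13, 0, 0, 7 and 3.

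For lists the share of splits with as many calls was 41 of 100 for pain (real 4, highest other 10), 86 for isoflurane (1 and 10), 18 for conditioning (6 and 9) and 29 for conditioning under isoflurane (4 and 9), each against baseline. It was 75 of 100 for conditioning minus pain (1 and 8), 21 for conditioning minus conditioning under isoflurane (5 and 8) and 25 for conditioning under isoflurane minus isoflurane (4 and 8). Chance is not excluded for any of these counts. A median of 2 to 3 lists was called in the other splits, so the preset correlation of 0.01 lets lists pass readily in these data.

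Correlations between the comparisons with baseline were also computed over all 126 splits of the baseline arrays into separate sets of 5 and 4. Their means lay between 0.0024 (pain and conditioning under isoflurane) and 0.169 (conditioning and conditioning under isoflurane), and single splits ranged from -0.302 (pain and conditioning under isoflurane) to 0.352 (conditioning and conditioning under isoflurane).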
